A study of Mus musculus with 62 samples.

How the data were processed

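Poly-A RNA from bladder tissue and from BBN963 cells had been extracted with miRNeasy columns and made into TruSeq libraries, per the labels. Every library was one replicate of one of 15 groups, read from the source names of the samples, and the sources say nothing on whether replicates were separate animals or cultures. Sample titles put the cell libraries into 2 experiments, and the second was sampled at 24 h and 72 h.

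The values analysed were gene-level signal tables deposited by the authors, who divided estimated read counts by DESeq2 normalisation factors, per the file headers. In the tissue tables and the first cell experiment the normalised values carried 1 factor per gene and library, so whole reads could not be recovered. In the second cell experiment the deposited signal values carried 1 size factor per library, and 100.0% of them came back to within 0.1 of a whole read. Log2 fold changes in the same files were computed by the authors with DESeq2, per the file headers. Adjusted p-values from DESeq2 were also deposited by the authors, and they were used here only to count the genes that each file marks. Per the submitters' processing notes, kallisto 0.44.0, DESeq2 (version not given), bcl2fastq 2.19 and the builds GRCm38.p6 and mm10 were used, with no role or order stated. Transcript annotation, kallisto settings and DESeq2 settings were not given in the sources used here. Pseudoalignment splits reads between near-identical transcripts, so single members of histone, protocadherin and other repeated families are uncertain. Gene coordinates were taken from the GENCODE M21 annotation of GRCm38.

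Several properties of the files were found by checking each table against its own columns. In the deposited table of rosiglitazone against DMSO 1655 entries stood beside the wrong gene, and they were realigned through the deposited mean; Actg1 had a mean of 2.905 before and 61658.999 after, which equals its deposited mean. In the tables of trametinib and of the combination 26 entries named by calendar dates were left out. In the 1-month table of 3 groups 126 genes had a deposited mean that differed from the mean of the columns. No copy was found among pairs of libraries within the 1-month tissue, the 5-day tissue or a cell experiment: the highest share of equal values above 100 was 1.38%, in the second cell experiment. Pairs across these sets were not compared. In the first cell experiment treated groups were joined through different factors per gene, so equal values could not show a copy between those groups.

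Before the data were examined, the design assumed counts or normalised values and named a test for each; since the files held normalised values, limma-trend was used throughout. Values were transformed as log2(value + 1), genes were kept with a value of at least 10 in as many libraries as the smallest group, and limma 3.58.1 was run in R 4.3.3 with trend and robust variance. All groups of a table were fitted together, and each gene was tested with a moderated t-test, adjusted by Benjamini and Hochberg over the genes tested and called at an adjusted p under 0.05. Tables normalised separately were never compared by level. Differences of effects between tables (1 month minus 5 days, first minus second cell experiment) were tested as interactions, in which a scale factor per gene and table drops out only for values well above the added 1. In the first cell experiment each treatment was compared with DMSO within its own table, and only for comparisons between treated groups and the interaction were the tables joined through the DMSO libraries they share.

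Gene lists, 30 in number, were fixed beforehand and tested with camera at a preset correlation of 0.01 between genes, for lists with at least 5 measured members, adjusted over the lists of a comparison. A correlation estimated from the data was the alternative, and fry, which tests direction alone and does not compare with other genes, was another. Counts adjusted over the list alone used only the list's own genes. Genes were named by a rule fixed beforehand: a panel of 19 genes; for each comparison with a control the 5 highest and 5 lowest called genes with a mean of at least 50 and complete separation of the groups, without predicted genes; and for each list the members with the lowest adjusted p, up to 4 in the majority direction and up to 2 in the other. Some genes that this rule selects are not reported here. Overlaps of calls were set against n1 × n2 / N, and for comparisons sharing controls 20 simulations with unchanged groups gave the correlation that sharing alone produces. Shared controls were also divided between the comparisons, planned where each part kept 2 libraries and added after the data were seen where 3 libraries were divided into 1 and 2.

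Alternatives were quantile normalisation, pseudocounts of 0.5 and 4, no filter on low values, only the compared groups in the fit, and every library left out once. Added after the data were seen were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads of the second cell experiment, the deposited 1-month table of 2 groups, a common scale for the first cell experiment with and without DMSO replicate 4, equal totals for joined tables, and thinning of the 5-day libraries to the depth of the shallowest. Each comparison was also repeated on other splits of its libraries, at most 100. Scripts in Python 3.11.15 (numpy 2.4.6, matplotlib 3.10.9) prepared the tables and drew the figures.

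Estimated depth differed between groups. It is the sum of a library's normalised values divided by its commonest value above 0, taken as 1 read. In the 5-day tissue only 10.8 to 35.0% of low values were whole multiples of that value, so depth there is a rough estimate. At 5 days the treated libraries had 17.4 to 22.9 M estimated reads (M, mega) and the vehicle libraries 32.7 to 72.4 M. The procedure was tested on simulated data with 200 changed genes. A log2 change of 1 was recovered in 36.7% of genes for the 1-month treatment, 18% for the 5-day treatment, 6% for the difference between them, 84% for trametinib in cells and 62% for the difference of ATRA effects, with no wrong sign. False calls were 0 to 10.8% of all calls, 1 of 1 moved lists and 0 of 20 unmoved lists were called, and 93 of 100 genes moved in both of 2 experiments were found. Draws without any change gave at most 2 calls. The numbers of simulated and real calls differed, and with them the cutoff set by the adjustment, so the recovered shares hold for the simulated data only. Every simulated library of a comparison had the same mean per gene, so differences in depth between libraries were not simulated.

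By the deposited adjusted p-values the authors' files mark 4902 genes for the 1-month treatment, 2474 for the 5-day treatment, 61 for rosiglitazone, 10534 for trametinib and 10553 for the combination in the first cell experiment. A sheet of the authors' pathway results lists PPAR signalling with a deposited q-value of 0.0156 (17 of 74 genes); how it was computed was not given in the sources used here.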

Results

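Messenger RNA was sequenced in 62 mouse samples that fall into 15 groups. In the animal part, basal bladder tumours had been induced with BBN, a nitrosamine carcinogen given to mice to produce muscle-invasive bladder cancer. Tumour-bearing mice received vehicle or the combination of rosiglitazone, an agonist of the nuclear receptor PPARG, and trametinib, an inhibitor of the kinase MEK. Treatment lasted 5 days (3 vehicle and 4 treated samples) or 1 month (3 vehicle and 4 treated samples), and 3 bladder samples came from animals without BBN. The culture part used BBN963, a mouse cell line of basal bladder cancer. A first cell experiment held 5 samples each of DMSO (the solvent control), rosiglitazone, trametinib and the combination at 72 h. A second cell experiment compared DMSO (3 samples at 24 h and 3 at 72 h), all-trans retinoic acid (ATRA, the ligand of the retinoic acid receptors; 6 and 5 samples) and the combination (4 and 4 samples). Estimated depth was 45.5 to 77.1 M reads (M, mega) per sample in the 1-month tissue table. At 5 days the vehicle samples had 32.7 to 72.4 M reads and the treated samples 17.4 to 22.9 M. The first cell experiment had 29.7 to 48.0 M reads per sample and the second 4.6 to 29.5 M.

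A panel of 19 genes was followed throughout. Their positions are given on the mouse build GRCm38, and all are protein-coding genes. The luminal differentiation factors were Pparg (chromosome 6, 115360951 to 115490399), Foxa1 (chromosome 12, 57540628 to 57546916) and Gata3 (chromosome 2, 9857078 to 9890034). Luminal surface genes were Upk1b (chromosome 16, 38773184 to 38800328), Upk2 (chromosome 9, 44452715 to 44454976), Upk3a (chromosome 15, 85017141 to 85022547) and Krt20 (chromosome 11, 99428403 to 99438150). Basal and squamous genes were Krt5 (chromosome 15, 101707070 to 101712898), Krt14 (chromosome 11, 100203162 to 100207548), Krt6a (chromosome 15, 101689910 to 101694307) and Trp63 (chromosome 16, 25683763 to 25892102). PPARG target genes were Fabp4 (chromosome 3, 10204088 to 10208576) and Angptl4 (chromosome 17, 33773750 to 33781830). Genes driven by ERK, the kinase below MEK, were Dusp6 (chromosome 10, 99263231 to 99267489), Spry4 (chromosome 18, 38586247 to 38601415) and Etv5 (chromosome 16, 22381309 to 22439719). Proliferation was followed with Mki67 (chromosome 7, 135689784 to 135716361), and the retinoic acid response with Cyp26a1 (chromosome 19, 37697798 to 37701536) and Rarb (chromosome 14, 16430839 to 16819156). Changes are log2 fold changes with their standard errors (SE). A gene was called at a limma adjusted p under 0.05, and lists of genes fixed beforehand were compared with all other genes by camera. The p-values measure the spread between these samples only, since nothing in the sample descriptions says whether replicates were separate animals or cultures. In all, 449 list tests were made, and list results lost when the correlation between genes was estimated are given with that p.

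The first question was how BBN tumours under vehicle differed from bladder without BBN (3 against 3 samples). Tumours carried high levels of keratinocyte keratins: Krt14 rose by 5.68 ± 0.78 (SE) and Krt6a by 7.21 ± 1.07, with adjusted p = 0.000722 and 0.00112. The luminal regulators fell together, Pparg by 2.05 ± 0.31, Gata3 by 1.65 ± 0.17 and Foxa1 by 1.52 ± 0.14, and the basal regulator Trp63 fell by 1.91 ± 0.43. For Pparg vehicle replicate 2 was the lowest, at a log2 value of 10.57 against 11.99 and 11.87 in replicates 1 and 3. The no-BBN mean of Pparg was 13.52. Mki67 rose by 3.04 ± 0.60. The uroplakins Upk1b, Upk2 and Upk3a had values of -0.64 ± 0.49, -1.35 ± 0.86 and -2.07 ± 1.33 and were not called. Vehicle replicate 2 alone was low for Upk1b, Upk2 and Upk3a. Its log2 value of Upk3a was 10.11 against 16.18 and 16.16 in replicates 1 and 3 and a no-BBN mean of 16.23. For Upk2 it was 9.88 against 13.66 and 13.57, with a no-BBN mean of 13.72. For Upk1b it was 13.8 against 16.1 and 15.9, with a no-BBN mean of 15.9. Rarb was lower by a log2 change of -0.78 ± 0.25, a call that was lost without any 1 of 4 libraries (vehicle replicates 1 and 3, no-BBN replicates 2 and 3), without a filter on low values, and when only the compared groups were fitted. The genes with the largest increases were Mcpt2 (8.86 ± 1.47), Cma2 (8.59 ± 1.67), Gabrp (8.53 ± 0.64), Mmp7 (8.47 ± 0.62) and Mcpt1 (8.34 ± 1.96). Mcpt1, Mcpt2 and Cma2 encode mast cell proteases and Mmp7 a matrix protease of epithelial tumours.

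Cell cycle genes rose in the tumours: 32 of 36 measured members were called higher and none lower (34 adjusted over the list alone), with Ccnb1 at 4.43 ± 0.63 and Ccne1 at 3.06 ± 0.41 (camera adjusted p = 4.14e-14; adjusted p = 0.314 with an estimated correlation). Of 34 interferon response genes 31 rose (33 adjusted over the list alone), among them Oas1a (3.38 ± 0.26) and Irf1 (2.60 ± 0.17), with adjusted p = 2.95e-17 and 0.262 with an estimated correlation. Immune cell markers moved with them. Of 26 T and NK cell genes 25 rose (26 adjusted over the list alone), including the regulatory T cell factor Foxp3 (7.65 ± 0.76) and the checkpoint receptors Pdcd1 (5.72 ± 0.43) and Ctla4 (7.57 ± 0.84), with adjusted p = 8.07e-17 and 0.262 with an estimated correlation. Neutrophil genes rose in 12 of 16 cases (13 adjusted over the list alone), and the list mean was 12.65 in vehicle replicate 2 against 9.26 and 8.46 in replicates 1 and 3 (adjusted p = 3.22e-05 and 0.443 with an estimated correlation). In the same comparison 17 of 22 fatty acid oxidation genes fell and none rose (18 adjusted over the list alone), such as Cpt1a, the gate of mitochondrial fatty acid import, by 1.43 ± 0.15 (adjusted p = 6.09e-08 and 0.262 with an estimated correlation). Among 30 PPARG target genes 10 fell and 1 rose, both over all genes and adjusted over the list alone, with Pdk4 falling by 4.04 ± 0.40 and Plin4 by 3.47 ± 0.47 (adjusted p = 0.000724 and 0.314 with an estimated correlation). The squamous list had 11 members called higher and 2 lower of 24 (13 and 2 adjusted over the list alone), with Krt16 at 7.91 ± 1.42 and Dsg3 at 4.44 ± 0.65 (adjusted p = 0.00417 and 0.443 with an estimated correlation). Vehicle replicate 2 stood apart in the direction of the change for the PPARG target list (9.22 against 10.01 and 10.15 in replicates 1 and 3) and the squamous list (10.66 against 8.69 and 8.79). In all, 4946 of 18762 genes were called, 2816 higher and 2130 lower. With quantile normalisation the median of all genes was -0.15, against -0.02 without it, and the split turned to 2386 higher and 2881 lower, and without no-BBN replicate 2 the count fell to 3217.

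The second question was what 1 month of rosiglitazone with trametinib did to the tumours (4 treated against 3 vehicle samples). The luminal regulators rose: Foxa1 by 1.11 ± 0.13 (adjusted p = 0.000422), Gata3 by 0.97 ± 0.16 (0.00201) and Pparg by 1.16 ± 0.29 (0.0172). These are values of whole tissue, in which basal and epithelial junction genes rose and immune cell genes fell as well, as given below. Whether the luminal rise came from a larger share of epithelial cells was not tested. Of 27 luminal genes 10 rose and 1 fell (12 and 1 adjusted over the list alone), among them the receptors Erbb3 (1.70 ± 0.21) and Erbb2 (1.41 ± 0.17) and the protease Tmprss2 (1.04 ± 0.12), with a median of 0.80 (adjusted p = 2.24e-05 and 0.259 with an estimated correlation). The list mean was 13.45 to 13.55 in the treated samples against 13.23 and 13.20 in vehicle replicates 1 and 3 and 11.71 in vehicle replicate 2. Krt14 (-0.87 ± 0.73), Krt6a (-1.91 ± 1.00), Upk3a (2.05 ± 1.25) and Krt5 (0.71 ± 0.40) were not called, nor were Mki67 (0.80 ± 0.56), Dusp6 (-1.17 ± 0.45) and Angptl4 (0.35 ± 0.41). Vehicle replicate 2 stood apart from replicates 1 and 3 in the direction of these values for Krt14 (18.88 against 15.29 and 15.80) and Upk3a (10.11 against 16.18 and 16.16). For Krt5 it stood apart the other way (17.46 against 15.66 and 15.71). For the called rise of Pparg it stood apart in the direction of the change (10.57 against 11.99 and 11.87). The treated mean of Pparg was 12.63. Of 20 basal genes 6 rose and none fell (7 and 1 adjusted over the list alone), led by Notch3 (2.06 ± 0.35) and Itgb4 (1.19 ± 0.28), with adjusted p = 0.000797 and 0.272 with an estimated correlation. Squamous genes moved the other way: 6 of 24 fell and 1 rose (7 and 1 adjusted over the list alone), with Serpinb2 falling by 2.92 ± 0.60 and Krt16 by 5.04 ± 1.32 (adjusted p = 0.0478 and 0.567 with an estimated correlation), and vehicle replicate 2 was the highest vehicle sample on this list (10.66 against 8.69 and 8.79). Without treated replicate 4 the lower values of Krt6a and Dusp6 were called, and without vehicle replicate 2 the higher value of Trp63. The call of Rarb (0.85 ± 0.24) was lost without vehicle replicate 1 or without treated replicate 2, 3 or 4.

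Genes of immune cells and of the interferon response fell broadly after 1 month. Of 26 T and NK cell genes 24 fell and none rose (25 adjusted over the list alone), and Pdcd1 fell by 3.46 ± 0.40 and Cd3d by 3.33 ± 0.46 (adjusted p = 1.39e-12 and 0.259 with an estimated correlation). Macrophage and dendritic cell genes fell in 16 of 22 cases (17 adjusted over the list alone), such as Fcer1g by 4.16 ± 0.39 and Cd68 by 2.72 ± 0.24 (adjusted p = 5.46e-11 and 0.259 with an estimated correlation). Of 34 interferon response genes 32 fell (33 adjusted over the list alone), with a median of -1.75 (adjusted p = 5.08e-16 and 0.259 with an estimated correlation). Antigen presentation genes of class II fell in 7 of 8 cases by both counts, 9 of 18 genes of class I fell (10 adjusted over the list alone), and B2m fell by 1.75 ± 0.21. Their adjusted p was 2.89e-05 and 3.73e-06, and 0.259 for both with an estimated correlation. Neutrophil genes fell in 6 of 16 cases (12 adjusted over the list alone), with a median of -3.90 and the uneven vehicle levels given above (adjusted p = 9.08e-05 and 0.456 with an estimated correlation). The largest decreases were in Mcpt1 (-7.48 ± 1.83), Exosc6 (-7.45 ± 2.21), Mcpt2 (-6.67 ± 1.38), Tpsab1 (-6.57; adjusted p = 0.0114) and Fcer1a (-6.54 ± 1.45), of which all but Exosc6 are expressed by mast cells. Haemoglobin and erythroid genes also fell, 7 of 8 by both counts, with Hbb-bs falling by 2.98 ± 0.47 (adjusted p = 4.88e-05 and 0.259 with an estimated correlation).

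Of 22 fatty acid oxidation genes 12 rose after 1 month and none fell (14 adjusted over the list alone), including Cpt1a (0.86 ± 0.14), with adjusted p = 4.6e-06 and 0.259 with an estimated correlation. Fatty acid synthesis genes rose in 9 of 16 cases (10 adjusted over the list alone), among them the lipogenic regulator Srebf1 (1.44 ± 0.21), with adjusted p = 9.08e-05 and 0.259 with an estimated correlation. Of 30 PPARG target genes 7 rose and none fell by both counts, with Plin4 at 2.43 ± 0.44 and Pdk4 at 1.74 ± 0.38 (adjusted p = 0.0467 and 0.513 with an estimated correlation). ERK pathway genes had 4 members called lower and 1 higher of 30 by both counts, with Dusp5 falling by 1.67 ± 0.22, Egr2 by 3.35 ± 0.65 and Spred2 rising by 0.87 ± 0.17 (adjusted p = 0.0307 and 0.616 with an estimated correlation). Epithelial junction genes rose in 10 of 20 cases and fell in 2 (13 and 2 adjusted over the list alone), with Grhl2 at 1.43 ± 0.23 and Tjp3 at 1.32 ± 0.19 (adjusted p = 8.36e-05 and 0.259 with an estimated correlation). The largest increases were in Spink1 (5.55 ± 1.48), Pcdhga2 (5.04 ± 1.15), Ankfn1 (4.79 ± 0.85), H2ac10 (4.33 ± 1.28) and Pcdhga10 (4.13 ± 1.21). The protocadherin and histone genes are uncertain, since they share exons or near-identical sequence with other members of their families. The calls of Spink1, H2ac10, Pcdhga10 and Exosc6 were each lost without any 1 of several libraries, vehicle replicate 1 among them for all but Pcdhga10. In all, 4464 of 18762 genes were called, 1889 higher and 2575 lower. With quantile normalisation the median of all genes was 0.13, against 0.04 without it, and the split turned to 2695 higher and 2102 lower. Vehicle replicate 2 stood apart on several of these lists: its fibroblast mean was 9.74 against 12.48 and 12.37 in replicates 1 and 3, and its endothelium mean 8.37 against 10.05 and 10.03. It also stood apart in the direction of the change for the PPARG target list (9.22 against 10.01 and 10.15) and the ERK pathway list (10.90 against 9.96 and 10.17).

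**Figure D1:**
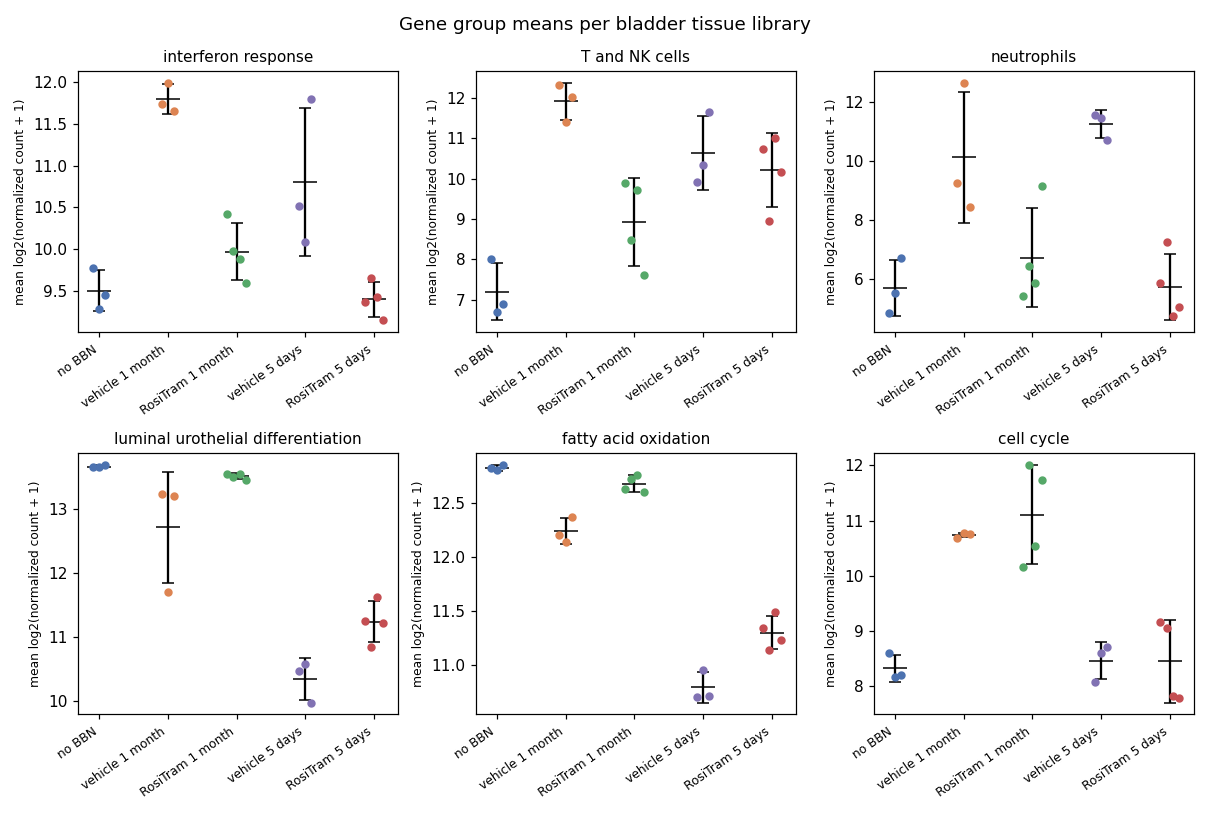
Mean log2 normalised values of gene lists in the tissue samples. Points are single libraries and dashes with bars are group means ± SD (n = 3 or 4); the 1-month and 5-day tables were normalised separately, so levels cannot be compared between them.

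The third question was what remained different from bladder without BBN after 1 month of treatment (4 against 3 samples). Proliferation genes were still high: Mki67 rose by 3.84 ± 0.56 (adjusted p = 0.00827), and 30 of 36 cell cycle genes were called higher and none lower (35 adjusted over the list alone), with Ccnb1 at 4.65 ± 0.59 (adjusted p = 7.75e-35 and 0.329 with an estimated correlation). Krt14 was higher by 4.80 ± 0.73 and Krt6a by 5.30 ± 1.00. Pparg (-0.89 ± 0.29) and Foxa1 (-0.41 ± 0.13) were not called, and Gata3 was called at -0.68 ± 0.16. These SE come from a fit that also holds the vehicle samples, where Pparg had an SD of 0.79. The mean log2 value of Pparg was 12.63 (SD 0.17) in treated and 13.52 (SD 0.13) in no-BBN samples, so the missing call does not show equal levels. Cholesterol synthesis genes rose in 9 of 23 cases (15 higher and 1 lower adjusted over the list alone), such as Idi1 (1.13 ± 0.14), with adjusted p = 9.73e-11 and 0.329 with an estimated correlation. T and NK cell genes were above bladder without BBN in 4 of 26 cases (13 adjusted over the list alone), including Pdcd1 (2.26 ± 0.40), whereas 4 of 22 macrophage and dendritic cell genes were below it (10 adjusted over the list alone), including C1qc (-2.19 ± 0.35). Their adjusted p was 1.88e-09 and 2.7e-05, and 0.546 for both with an estimated correlation. Gjb1 (7.88 ± 0.56), Mmp7 (7.52 ± 0.58) and Gabrp (6.80 ± 0.60) had the largest increases, and Hal (-4.92 ± 0.83), Nat8l (-4.75 ± 0.69) and Fmo5 (-4.71 ± 0.27), enzymes of amino acid and xenobiotic metabolism, the largest decreases. In all, 753 of 18762 genes were called, 482 higher and 271 lower. This count moved to 1407 when only the compared groups were fitted, and to 136, 160, 384 and 470 without no-BBN replicate 2, no-BBN replicate 3, treated replicate 2 and treated replicate 3. The calls of Hal, Pdcd1 and C1qc were lost without no-BBN replicate 2 or 3, that of Krt6a without any 1 of the 3 no-BBN samples, and that of Krt14 without no-BBN replicate 2. The call of Gata3 was lost under quantile normalisation and without any 1 of the compared libraries except no-BBN replicate 3.

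Of the genes higher in vehicle tumours than in bladder without BBN, 1792 were lower after 1 month of treatment, where independent lists would share 386.5, and 1277 lower genes were higher after treatment, where 214.5 would be shared. The log2 changes had r = -0.762 across 18762 genes, which are not independent of each other. Both comparisons use the same vehicle libraries, and unchanged groups simulated against them gave r = -0.536. The covariance was -1.21 against -0.172 in the simulation. With the 3 vehicle libraries divided between the comparisons, a check added after the data were seen, r was -0.489 at the median of 6 divisions (-0.582 to -0.377).

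At 5 days the question was which changes come early (4 treated against 3 vehicle samples). Neutrophil genes fell in 14 of 15 cases (15 adjusted over the list alone) with a median of -5.47, among them Mmp9 by 5.47 ± 0.58 and Csf3r by 5.45 ± 0.64 (adjusted p = 1.3e-15 and 0.223 with an estimated correlation), and the list mean was 4.75 to 7.25 in treated and 10.72 to 11.57 in vehicle samples. Macrophage and dendritic cell genes fell in 13 of 22 cases (15 adjusted over the list alone), such as Cd14 by 4.56 ± 0.47, and 10 of 28 cytokine genes fell (16 adjusted over the list alone), such as Il1rn by 6.71 ± 0.62 and Il1a by 5.10 ± 0.57. Their adjusted p was 2.87e-13 and 3.45e-09, and 0.247 and 0.223 with an estimated correlation. Dusp6 fell by 2.08 ± 0.32 (adjusted p = 0.011), and 7 of 30 ERK pathway genes fell (8 adjusted over the list alone), including Egr1 by 3.85 ± 0.44 and Plaur by 3.30 ± 0.32 (adjusted p = 0.000232 and 0.451 with an estimated correlation). Of 34 interferon response genes 7 fell (20 adjusted over the list alone), such as Isg15 by 3.06 ± 0.45 (adjusted p = 6.47e-10 and 0.363 with an estimated correlation), and 7 of 8 class II antigen presentation genes fell (all 8 adjusted over the list alone; adjusted p = 4.22e-09 and 0.223 with an estimated correlation).

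Luminal genes rose in 3 of 27 cases and fell in 1 at 5 days (10 and 1 adjusted over the list alone), with Erbb2 at 1.20 ± 0.22 and Krt8 at 1.12 ± 0.24 (adjusted p = 4.2e-06 and 0.247 with an estimated correlation). These too are values of whole tissue, in which immune cell genes fell. Whether the luminal rise came from a larger share of epithelial cells was not tested. Fatty acid oxidation genes had 1 member called higher of 22, Acaa2 at 0.94 ± 0.15 (8 higher and 1 lower adjusted over the list alone; adjusted p = 1.35e-06 and 0.25 with an estimated correlation). Pparg (0.36 ± 0.39), Foxa1 (1.46 ± 0.57), Gata3 (1.28 ± 0.56), Krt14 (0.83 ± 0.90) and Mki67 (-0.70 ± 0.55) were not called. Gria4 (3.30 ± 0.55) and Chl1 (2.79 ± 0.44) had the largest increases, and Spatc1 (-8.00 ± 1.34), Mrgpra2b (-7.86 ± 1.06) and Mrgpra2a (-7.79 ± 1.12) the largest decreases. The 2 Mrgpra2 genes are near-identical copies, and their separate values are uncertain. In all, 1043 of 16891 genes were called, 118 higher and 925 lower. With quantile normalisation the median of all genes was 0.15, against 0.04 without it, and the calls were 249 higher and 785 lower. The count moved to 428, 531, 602 and 589 without vehicle replicate 1, vehicle replicate 3, treated replicate 1 and treated replicate 3. The calls of Erbb2 and Krt8 were lost without any 1 of those 4 libraries or treated replicate 2, and those of Acaa2, Gria4 and Spatc1 without vehicle replicate 1.

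Changes at 1 month and 5 days were compared directly. Across 16617 genes tested at both times, 633 were lower at both, where independent lists would share 135.2, and 64 were higher at both, where 12.4 would be shared (r = 0.586 across genes). The difference between the effects was called by limma for 1 gene, Zfand2a, a stress-induced gene chosen after its value was seen, at 1.55 ± 0.19 (adjusted p = 0.0255), with 2867 genes at an unadjusted p under 0.05. T and NK cell genes had lower values at 1 month than at 5 days relative to vehicle, with a median difference of -2.79, no member called and 20 of 26 lower adjusted over the list alone (adjusted p = 1.73e-11 and 0.645 with an estimated correlation). Neutrophil genes had a median difference of 2.02 with none called by either count (adjusted p = 0.00682 and 0.782 with an estimated correlation). Quantile normalisation gave 26 calls and a pseudocount of 4 gave 4, and without vehicle 1-month replicate 2, the library with the high neutrophil mean, 126 genes were called. No gene was called without 1-month vehicle replicate 1 or 3, 1-month treated replicate 1 or 2, or 5-day treated replicate 1 or 3, and 2, 6 and 3 genes without 1-month treated replicate 3, 1-month treated replicate 4 and 5-day vehicle replicate 2. In simulated data this test recovered 37.5% of genes with a log2 difference of 2. Those data gave 45 calls against 1 in the real data, so their cutoff was looser. The recovery may therefore overstate what the real test could find.

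Upk1b, Upk3a, Krt20, Krt5 and Cyp26a1 were too low in the cells to be tested. Rosiglitazone alone was tested in the first cell experiment (5 against 5 samples) to ask what PPARG activation does without MEK inhibition. No gene of 14218 was called by limma, with 940 at an unadjusted p under 0.05. The fatty acid oxidation list was higher as a group, with a median of 0.08 and 4 of 22 members higher adjusted over the list alone (camera adjusted p = 1.19e-06 and 0.116 with an estimated correlation), and the PPARG target list had a median of 0.08 with 5 of 22 higher adjusted over the list alone (adjusted p = 3.81e-05 and 0.116 with an estimated correlation). Squamous genes had a median of -0.13 with 2 of 14 lower adjusted over the list alone (adjusted p = 4.4e-05 and 0.116 with an estimated correlation). Angptl4 had a value of 0.45 ± 0.11, Krt6a of -0.60 ± 0.09 and Pparg of -0.15 ± 0.10, none of them called. DMSO replicate 4 lay apart from the other DMSO samples on the second principal component (-43.1 against 10.6 to 14.1). Without it 71 genes were called, 26 higher and 45 lower, including the PPARG targets Hilpda (0.34), Cpt1a (0.28) and Plin2 (0.22) and Krt6a (-0.58). Bringing all 4 groups to a common scale, a setting added after the data were seen, gave 75 calls, 24 higher and 51 lower, of which 29 were shared with those 71. The common scale without DMSO replicate 4 gave 320 calls, 150 higher and 170 lower, and no filter on low values gave 5. Without rosiglitazone replicate 4 the count was 3, and without any 1 of DMSO replicate 5 and the other rosiglitazone samples it was 1. The deposited table marks 61 genes at an adjusted p under 0.05. Simulated log2 changes of 0.5 were recovered in 69.4% of genes for this comparison. The simulated data also held larger changes and gave 184 calls, and more calls loosen the cutoff set by the adjustment. With no gene called in the real data that cutoff was stricter, and Krt6a at -0.60 had a limma adjusted p of 0.0681. The recovery of 69.4% therefore does not show that changes of 0.5 were absent.

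Trametinib alone lowered the genes that ERK drives (5 against 5 samples). Dusp6 fell by 5.49 ± 0.08, Spry4 by 6.09 ± 0.45 and Etv5 by 7.65 ± 0.35, and 26 of 28 ERK pathway genes fell and 1 rose, by both counts, with a median of -2.19, including Ccnd1 by 3.22 ± 0.04 and Fosl1 by 3.78 ± 0.08 (adjusted p = 9.64e-13 and 0.00184 with an estimated correlation). All 36 cell cycle genes fell, with a median of -1.23 and Mki67 falling by 1.47 ± 0.04 (adjusted p = 1.1e-16 and 0.166 with an estimated correlation). Of 32 interferon response genes 30 rose and 1 fell, with Irf7 at 2.42 ± 0.08 and Gbp2 at 1.99 ± 0.06 (adjusted p = 3.04e-11 and 0.183 with an estimated correlation), and 15 of 18 class I antigen presentation genes rose and 2 fell, with Tapbp at 1.63 ± 0.04 and B2m at 1.29 ± 0.04 (adjusted p = 1.53e-05 and 0.192 with an estimated correlation). Differentiation genes rose as well: 13 of 19 luminal genes, led by Tmprss2 (2.48 ± 0.04), 13 of 15 basal genes, led by Lamb3 (2.33 ± 0.04), and 12 of 18 squamous genes, led by Sprr1a (5.18 ± 0.07), with 2, 2 and 0 members lower. Their adjusted p was 0.00483, 0.000494 and 0.000494, and 0.183, 0.132 and 0.132 with an estimated correlation. Pparg rose by 0.77 ± 0.07, Foxa1 by 0.79 ± 0.04, Krt14 by 2.80 ± 0.07 and Angptl4 by 1.83 ± 0.07. Of 16 retinoic acid response genes 12 rose and 1 fell, with Dhrs3 at 2.46 ± 0.07 and Rarb at 1.78 ± 0.09 (adjusted p = 0.000467 and 0.0399 with an estimated correlation). Glycolysis and hypoxia genes fell in 19 of 21 cases and rose in 2, with Eno1 falling by 1.12 ± 0.04 (adjusted p = 3.89e-07 and 0.183 with an estimated correlation). The counts adjusted over the list alone were the same for each of these lists. The largest changes were in Cntnap2 (6.06 ± 0.19) and Krt15 (5.62 ± 0.24) upward and in Etv4 (-8.01 ± 0.38) and Il1a (-7.42 ± 0.09) downward. In all, 10249 of 14414 genes were called, 5159 higher and 5090 lower.

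The combination gave much the same picture in the first cell experiment (5 against 5 samples). Against DMSO, 28 of 29 ERK pathway genes fell and 1 rose (adjusted p = 2.58e-12 and 0.00122 with an estimated correlation), with Dusp6 falling by 5.86 ± 0.17. All 36 cell cycle genes fell, with a median of -1.44 (adjusted p = 4.29e-17 and 0.0913 with an estimated correlation), and 31 of 33 interferon response genes rose and 1 fell (adjusted p = 6.34e-11 and 0.146 with an estimated correlation). Those counts were unchanged when adjusted over the list alone. Sprr1a rose by 5.74 ± 0.06, Krt14 by 2.30 ± 0.07, Pparg by 0.62 ± 0.08 and Angptl4 by 2.86 ± 0.07. In all, 10310 of 14220 genes were called, 5162 higher and 5148 lower. Against rosiglitazone alone 10903 of 15004 genes were called, 5447 higher and 5456 lower, with all 36 cell cycle genes lower (adjusted p = 6.94e-19 and 0.0536 with an estimated correlation) and Dusp6 falling by 5.96 ± 0.14. Trametinib and the combination shared 4686 higher and 4734 lower genes with DMSO as the common control, where independent lists would share 1850.4 and 1840.6 (r = 0.969 across genes, 0.5 in simulated unchanged groups; covariance 0.731 against 0.015). With the DMSO samples split between the comparisons, the median r was 0.914.

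What rosiglitazone added to trametinib was read from the combination against trametinib alone (5 against 5 samples in a fit of 20). The largest increases were in Acaa1b (1.32 ± 0.10), a peroxisomal enzyme of fatty acid oxidation, and Angptl4 (1.03 ± 0.08), both with adjusted p = 2.33e-08, and the largest decreases in Cbs (-1.17 ± 0.14) and Serpinb1b (-1.16 ± 0.25). Cell cycle genes fell further in 21 of 36 cases (25 lower and 1 higher adjusted over the list alone), by a median of -0.18, with Mki67 falling by 0.18 ± 0.04 (adjusted p = 1.07e-18 and 0.126 with an estimated correlation). Cholesterol synthesis genes fell in 9 of 23 cases and rose in 1 (15 and 1 adjusted over the list alone) (adjusted p = 2.71e-09 and 0.126 with an estimated correlation). Fatty acid oxidation genes rose in 3 of 22 cases and fell in 1 (5 and 1 adjusted over the list alone), with Cpt1a at 0.36 ± 0.04 (adjusted p = 0.00157 and 0.276 with an estimated correlation). Krt14 fell by 0.49 ± 0.07 and Krt6a by 0.29 ± 0.08, the latter a call lost without any 1 of 4 libraries (trametinib replicates 1 and 4, combination replicates 2 and 3), and Pparg (-0.14 ± 0.09), Foxa1 (0.01 ± 0.03) and Dusp6 (-0.38 ± 0.14) were not called. In all, 1049 of 15004 genes were called, 470 higher and 579 lower, 29 of them by at least 2-fold, and fitting only the compared groups gave 2041. Whether rosiglitazone acted differently with and without trametinib was tested as an interaction. It was called for 272 genes, 112 higher and 160 lower, including Angptl4 (0.58 ± 0.11), Ccna2 (-0.27 ± 0.04) and Mki67 (-0.26 ± 0.05), the last lost under quantile normalisation. Cell cycle genes were lower than additive in 15 of 36 cases (21 adjusted over the list alone; adjusted p = 1.65e-19 and 0.101 with an estimated correlation). Without DMSO replicate 4 the interaction was called for 1205 genes and without rosiglitazone replicate 4 for 179.

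**Figure D2:**
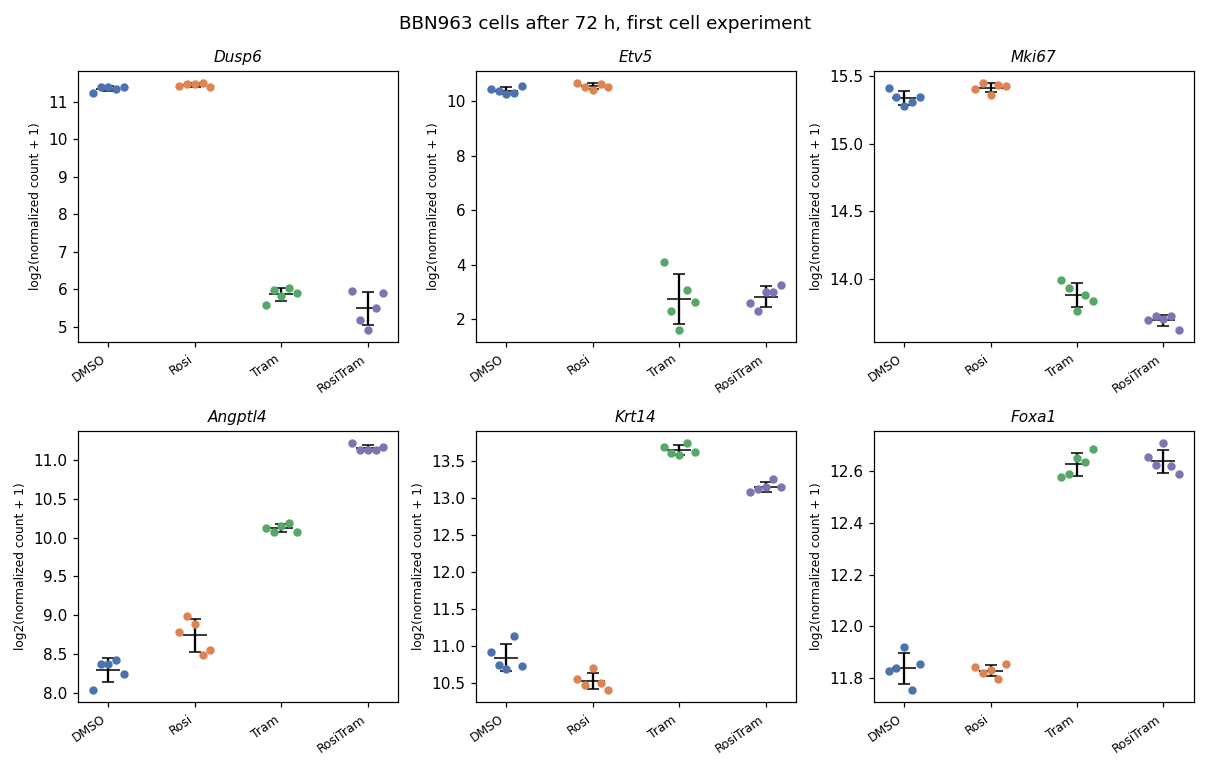
Log2 normalised values of panel genes in the first cell experiment at 72 h. Points are single libraries and dashes with bars are group means ± SD (n = 5); Dusp6 fell by 5.49 under trametinib and by 5.86 under the combination.

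In the second cell experiment the combination was followed over time (4 treated against 3 DMSO samples at each time). At 24 h all 36 cell cycle genes fell with a median of -1.83, and at 72 h all 36 with a median of -3.18, with Mki67 falling by 1.95 ± 0.24 and 3.94 ± 0.24 (adjusted p = 4.34e-21 and 1.67e-18, and 0.186 and 0.252 with an estimated correlation). Of 28 ERK pathway genes 24 fell at 24 h and 25 at 72 h and none rose, with medians of -1.68 and -3.22 and Dusp6 falling by 4.84 ± 0.20 and 6.74 ± 0.20 (adjusted p = 1.37e-13 and 1.41e-11, and 0.118 and 0.206 with an estimated correlation). Interferon response genes rose in 26 and 27 of 32 cases, with 0 and 2 lower (26 and 1 at 24 h adjusted over the list alone), and Ifih1 at 1.53 ± 0.18 and 2.27 ± 0.18 (adjusted p = 2.11e-09 and 2.75e-07, and 0.186 and 0.252 with an estimated correlation). Class I antigen presentation genes rose in 15 and 16 of 18 cases, with B2m at 0.79 ± 0.12 and 2.32 ± 0.12 (adjusted p = 2.35e-05 and 4.88e-06, and 0.268 and 0.252 with an estimated correlation). Fatty acid oxidation genes rose in 18 and 17 of 22 cases (19 and 17 adjusted over the list alone), with Cpt1a at 1.11 ± 0.16 and 2.13 ± 0.16 (adjusted p = 5.11e-06 and 0.000228, and 0.268 and 0.415 with an estimated correlation). Cholesterol synthesis genes rose in 7 of 23 cases at 24 h and fell in 2, and at 72 h they fell in 20 and rose in 1 (adjusted p = 0.598 and 3.96e-07, and 0.902 and 0.256 with an estimated correlation). The list counts not given separately were equal when adjusted over the list alone. Foxa1 rose by 0.52 ± 0.15 and 1.22 ± 0.15 and Rarb by 1.99 ± 0.22 at 72 h. Krt14 (-0.04 ± 0.32 and -0.36 ± 0.32) and Angptl4 (0.46 ± 0.52 and -0.33 ± 0.52) were not called. The SE of Angptl4 comes from a fit that also holds the ATRA samples, where its SD was 1.13 at 24 h and 0.77 at 72 h. Its mean log2 value at 24 h was 7.36 (SD 0.17) in treated and 6.90 (SD 0.21) in DMSO samples. At 72 h these means were 7.57 (SD 0.31) and 7.90 (SD 0.15). Pparg was lower at 24 h (-0.39 ± 0.15), a call lost under DESeq2 and without DMSO replicate 1 or treated replicate 2 or 3. The largest changes at 72 h were in Fbln7 (5.93 ± 0.40) upward and Il1a (-7.43 ± 0.27) and Il24 (-7.25 ± 0.65) downward.

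Of 14014 genes, 7694 were called at 24 h (3882 higher and 3812 lower) and 9731 at 72 h (4816 higher and 4915 lower), of which 3388 higher and 3398 lower were shared, where independent lists would share 1334.1 and 1336.9 (r = 0.809 across genes). The effect at 72 h minus that at 24 h was called for 3443 genes, 1663 higher and 1780 lower. Cholesterol synthesis genes were lower at 72 h than at 24 h in 21 of 23 cases, by both counts, with a median of -1.20 and Insig1 at -1.52 ± 0.11 (adjusted p = 5.14e-21 and 0.136 with an estimated correlation). Cell cycle genes were lower in 30 of 36 cases (32 adjusted over the list alone; adjusted p = 3.98e-18 and 0.318 with an estimated correlation) and ERK pathway genes in 18 of 28 by both counts (adjusted p = 7.58e-09 and 0.143 with an estimated correlation). Class I antigen presentation genes were higher in 7 of 18 cases (11 higher and 1 lower adjusted over the list alone), with H2-K1 at 1.25 ± 0.15 (adjusted p = 3.27e-05 and 0.376 with an estimated correlation). Rarb (1.75 ± 0.31), Dusp6 (-1.90 ± 0.29) and Mki67 (-1.98 ± 0.34) differed between the times, as did Foxa1 (0.69 ± 0.21), a call lost under quantile normalisation. For Rarb the control moved: its mean normalised value was 51.86 at 24 h and 50.25 at 72 h in treated samples, but 43.76 and 11.84 in DMSO samples. Foxa1 fell with time in both, from 2672 to 2180 in treated and from 1861 to 936.8 in DMSO samples.

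ATRA was compared with DMSO to ask how the same cells respond to retinoic acid (6 against 3 samples at 24 h and 5 against 3 at 72 h). The chloride channel regulator Clca1 rose most, by 7.37 ± 0.44 at 24 h and 6.43 ± 0.45 at 72 h, and the basal keratin Krt14 fell by 2.90 ± 0.29 and 2.41 ± 0.30. Retinoic acid response genes rose in 7 of 17 cases at both times and fell in 3 and 1 (7 and 3, and 8 and 2, adjusted over the list alone), among them the retinoid enzymes Dhrs3 (2.57 ± 0.19 and 4.32 ± 0.19) and Cyp26b1 (4.22 ± 0.27 and 3.08 ± 0.28) and the receptor Rarb (1.46 ± 0.20 and 2.35 ± 0.21), with adjusted p = 0.00183 and 3.77e-05, and 0.163 and 0.0602 with an estimated correlation. Pparg rose by 0.96 ± 0.14 and 0.98 ± 0.14 and Krt6a fell by 2.28 ± 0.31 and 1.86 ± 0.32. Epithelial-mesenchymal transition genes fell in 9 and 6 of 15 cases and rose in 0 and 1 (9 and 0, and 8 and 1, adjusted over the list alone), with Vim falling by 1.59 ± 0.11 and 1.46 ± 0.11 (adjusted p = 0.00148 and 0.0012, and 0.0337 and 0.0355 with an estimated correlation). Fatty acid oxidation genes rose in 13 and 11 of 22 cases (14 and 12 adjusted over the list alone), with Eci2 at 0.94 ± 0.11 and 0.89 ± 0.12 (adjusted p = 4.98e-06 and 1.87e-06, and 0.312 and 0.411 with an estimated correlation). Luminal genes rose in 6 and 7 of 19 cases and fell in 1 each time (8 and 1 at both adjusted over the list alone), with Krt19 at 1.41 ± 0.14 and 1.72 ± 0.14 (adjusted p = 0.00148 and 0.000856, and 0.163 and 0.142 with an estimated correlation). Cell cycle genes fell in 21 of 36 cases at 24 h (27 adjusted over the list alone) and none was called at 72 h by either count (adjusted p = 1.28e-07 and 0.000738, and 0.485 and 0.668 with an estimated correlation).

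In all, 3554 of 14014 genes were called for ATRA at 24 h (1753 higher and 1801 lower) and 2344 at 72 h (1342 higher and 1002 lower), with 889 higher and 745 lower shared, where independent lists would share 167.9 and 128.8 (r = 0.656 across genes). The 24 h count moved to 2129 and 2228 without DMSO replicate 1 and 3. The 72 h count moved to 1326 and 1421 without DMSO replicate 1 and 2, and to 731 when only the compared groups were fitted. ATRA 72 h replicate 1 stood apart from the other 4: its log2 value was 11.69 for Mki67 (12.79 to 12.90 in the others), 10.82 for Dhrs3 (9.43 to 9.64) and 9.07 for Clca1 (6.61 to 7.17). The time label of this library is in doubt, as set out in the closing section, and every ATRA 72 h value given here includes it unless it is said to be left out. Angptl4, not called at either time (0.76 ± 0.48 and 0.57 ± 0.50), was high in that library (9.82 against 7.94 to 8.23) and in ATRA 24 h replicate 6 (9.96 against 7.15 to 7.25). The effect at 72 h differed from that at 24 h for 7 genes, 2 higher and 5 lower, with 718 at an unadjusted p under 0.05. Among them, chosen after their values were seen, were Dhrs3 (1.75 ± 0.27), Anxa6 (0.56 ± 0.10) and the death receptor Fas (-1.96 ± 0.34). The mean normalised value of Dhrs3 was lower at 72 h than at 24 h under ATRA (951.6 against 1780) and still more so under DMSO (43.21 against 298.9). The count of 7 genes became 160 without ATRA 72 h replicate 1. It was 3 and 2 without DMSO 24 h replicates 1 and 2, and 1 and 2 without DMSO 72 h replicates 1 and 3. It was 3 with quantile normalisation, 0 when only the compared groups were fitted, 29 by DESeq2 and 7 by edgeR.

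**Figure D3:**
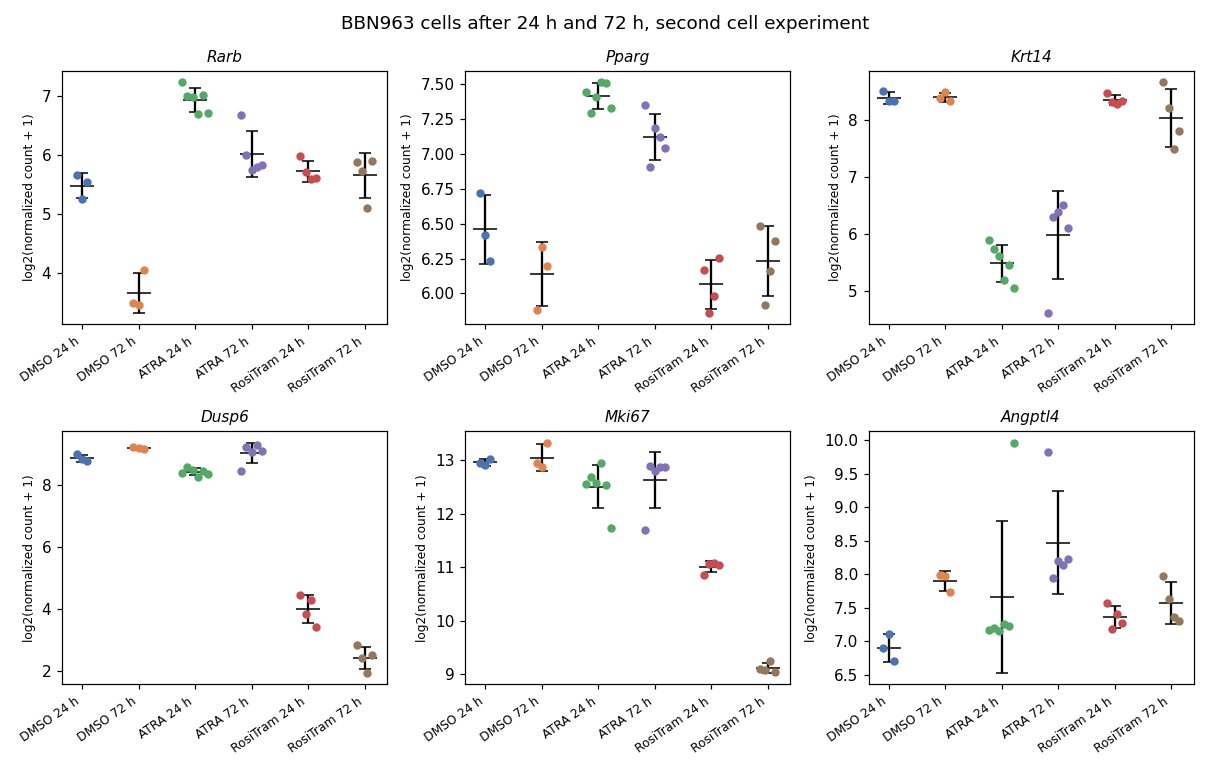
Log2 normalised values of panel genes in the second cell experiment at 24 h and 72 h. Points are single libraries and dashes with bars are group means ± SD (n = 3 to 6); ATRA 72 h replicate 1 and ATRA 24 h replicate 6 are the libraries with Angptl4 near 10.

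The combination and ATRA shared 1430 higher and 1382 lower genes at 24 h, where independent lists would share 485.6 and 489.9, and 1108 and 772 at 72 h, where 461.2 and 351.4 would be shared. Their log2 changes had r = 0.668 and 0.561 across genes, and simulated unchanged groups against the same DMSO samples gave 0.619 and 0.594. The covariance was 0.275 and 0.319 against 0.056 in both simulations. With the 3 DMSO samples of each time divided between the comparisons, a check added after the data were seen, the median r over 6 divisions was 0.424 at 24 h (0.402 to 0.471) and 0.467 at 72 h (0.382 to 0.479).

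The combination was given in both cell experiments at 72 h (5 against 5 and 4 against 3 samples). They shared 3558 higher and 3617 lower genes, where independent lists would share 1746 and 1696.5 (r = 0.759 across 12676 genes). The sizes differed for 7075 of 15038 genes, 3658 higher and 3417 lower in the first experiment, a balance that quantile normalisation turned (3393 higher and 4080 lower). The 15038 genes were filtered over both experiments together and include genes outside the 12676 tested in each. All 36 cell cycle genes fell less in the first experiment, with a median difference of 1.78 and Mki67 at 2.29 ± 0.10 (adjusted p = 2.02e-30 and 0.00842 with an estimated correlation). Cholesterol synthesis genes were higher in 22 of 23 cases (22 and 1 lower adjusted over the list alone), with Idi1 at 2.26 ± 0.06 (adjusted p = 5.77e-19 and 0.00842 with an estimated correlation), as were 10 of 16 fatty acid synthesis genes by both counts, with 3 lower and Fasn at 1.63 ± 0.11 (adjusted p = 0.00415 and 0.0361 with an estimated correlation). Angptl4 (3.19 ± 0.16), Krt14 (2.66 ± 0.24) and Krt6a (1.51 ± 0.16) were higher and Etv5 (-2.28 ± 0.32) and Foxa1 (-0.42 ± 0.06) lower in the first experiment, and the difference of Pparg (0.53 ± 0.17) was lost under quantile normalisation and without DMSO 72 h replicate 2 of the second. Under the combination Etv5 lay near the added 1 in both experiments (mean log2 values of 2.82 and 2.41). A scale factor does not drop out at such values, so the size of its difference is uncertain. The experiments differ in more than treatment, and those differences cannot be separated from the experiment.

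Between tissue and cells the changes were nearly uncorrelated. The combination at 1 month in tumours and in the first cell experiment shared 853 higher genes, where independent lists would share 594.2, and 706 lower genes, where 681.4 would be shared (r = 0.054 across 13607 genes). At an adjusted p under 0.01 the shared genes numbered 350 and 254, where 209.3 and 291.7 would be shared. With the second experiment at 72 h 754 higher and 590 lower genes were shared, where 569.1 and 612 would be (r = 0.053). Interferon response genes fell in the tumours in 32 of 34 cases and rose in the cells in 31 of 33 (camera adjusted p = 5.08e-16 and 6.34e-11, and 0.259 and 0.146 with an estimated correlation), a difference not tested directly. Cpt1a rose in both, by 0.86 ± 0.14 in tumours and 1.89 ± 0.04 in cells.

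**Figure D4:**
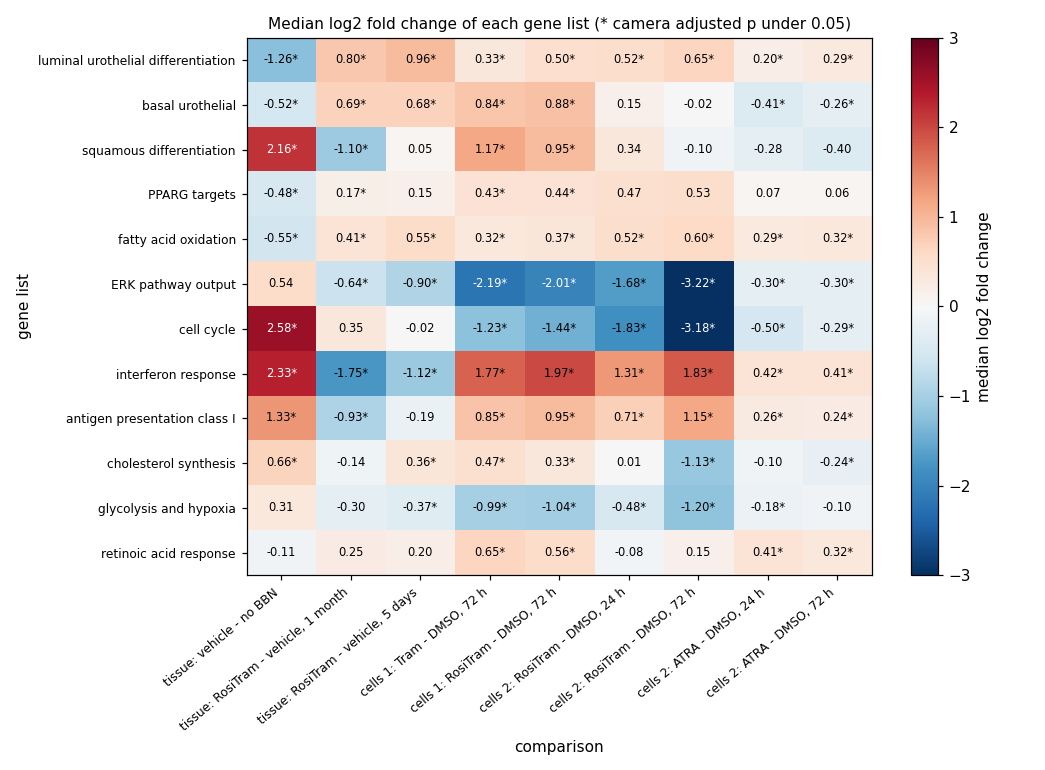
Heat map of the median log2 fold change of selected gene lists (vertical axis) in selected comparisons (horizontal axis). Colours give the median over the measured members and asterisks mark a camera adjusted p under 0.05. The T and NK cell list, which is not drawn here, had a median of 4.52 in vehicle tumours against bladder without BBN.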

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

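The tests of differences between effects, the quantile setting and leaving out single libraries were planned; the swap test in the 1-month tissue and the thinning test were added later with bounds written before their own results; and the other tests, with the use of the quantile setting as a test of cause, were chosen only after the result was seen. A library was singled out where its gap to the nearest of its group was large for the group's range (Dixon's test at 95%), which chance does in about 1 in 20 groups. This rule was applied only in the 10 groups of 4 to 10 libraries. Groups of 3 libraries were not examined by it, so it could not single out vehicle 1-month replicate 2.

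In the second cell experiment, ATRA 72 h replicate 1 was far from the other 4 libraries for 15 genes. Its log2 values were higher for Angptl4 (9.82), Clca1 (9.07), Dhrs3 (10.82), Foxa1 (11.20), Rarb (6.68) and Synpo (10.68) and lower for Calcb (6.24), Dusp6 (8.43), Etv5 (6.25), Krt14 (4.63), Krt6a (4.01), Mki67 (11.69), Prl2c2 (4.63), Spry4 (3.42) and Timp3 (4.56). ATRA 24 h replicate 6 was far from its group for Angptl4 (9.96), Fbn1 (4.58), Mki67 (11.74), Prl2c2 (4.22) and the share of the 10 highest genes (6.822%).

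One explanation is a wrong time label of ATRA 72 h replicate 1: on an axis of 1904 genes that separates DMSO at 24 h (-0.03 to 0.03) from DMSO at 72 h (0.50 to 0.56) it lies at 0.01, among ATRA 24 h libraries (-0.03 to 0.04) and away from the other ATRA 72 h libraries (0.43 to 0.44), so the label may be wrong. Its sample number also falls among the numbers of samples labelled 24 h. The position does not settle it, since the combination at 72 h also lies at 0.02 to 0.11. A swap with an ATRA 24 h library is argued against, since the highest of those lies at 0.04. A treatment or handling shared with ATRA 24 h replicate 6 alone stays open: the deviations of both from the other ATRA 24 h libraries had r = 0.411 across 14014 genes, against at most 0.141 for any other ATRA library, below the bound of 0.5 set for it. No biological explanation was tested, as the design gives none for a single library; without it the difference of ATRA effects between times was called for 160 genes in place of 7.

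Among the 1-month tumours, vehicle replicate 2 had higher neutrophil, squamous and cytokine list means than replicates 1 and 3 (by 3.78, 1.92 and 1.92) and lower fibroblast, luminal, macrophage and T and NK cell means (by 2.68, 1.51, 1.07 and 0.77). Its depth of 73.3 M reads lies between those of the other replicates, which argues against depth. A swap with another 1-month group is argued against, since 0 libraries of those groups lay nearer to vehicle replicates 1 and 3 than to their own. A lower share of smooth muscle and fibroblast RNA alone is argued against by a neutrophil shift that exceeds the luminal shift by 5.29. Differences between tumours in their cells, or in the part sampled, stay open, and no biological explanation was tested.

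At 5 days 88.7% of the calls were lower in treated tissue, where the treated libraries were also the shallower ones. Thinned to equal estimated depth, 87.9% of calls were lower, which argues against depth as the cause as far as that estimate holds. Whole reads could not be recovered in tissue, so the thinning was approximate. After quantile normalisation 75.9% were lower, which argues against the normalisation of the deposited values as the whole cause. The treatment itself stays open as a biological hypothesis, found and tested on the same data, and a change in the share of cell types stays untested.

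Single libraries singled out by the same rule, with no explanation offered, were these. In the cells they were Calcb at 6.66 in ATRA 24 h replicate 4, Trp63 at 2.85 in DMSO replicate 5, Slc16a6 at 4.92 in combination replicate 1 and Etv4 at 9.61 in rosiglitazone replicate 2 of the first experiment, and Mki67 at 10.85 in combination 24 h replicate 1 of the second. In tissue they were Exosc6 at 7.34 in treated 1-month replicate 3 (0 in the others), Krt14 at 16.77 and Upk3a at 14.88 in treated 1-month replicate 4, Foxa1 at 11.65 and Gata3 at 12.37 in treated 5-day replicate 4, Gria4 at 8.56 in treated 5-day replicate 1 and Upk2 at 8.28 in treated 5-day replicate 2. Over all genes and library measures examined in the groups of 4 to 10 libraries, 32 of 258 tests singled out a library.

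Effects that differed between groups by a test of the difference were these. The treatment effect at 1 month minus 5 days was called for 1 gene, and the effect of rosiglitazone with and without trametinib for 272 genes, with Angptl4 at 0.58 and Mki67 at -0.26. The ATRA effect at 72 h minus 24 h was called for 7 genes. The combination's effect at 72 h minus 24 h was called for 3443 genes, with Foxa1 at 0.69, Dusp6 at -1.90, Mki67 at -1.98 and Rarb at 1.75. Its effect in the first minus the second cell experiment was called for 7075 genes, with Pparg at 0.53, Foxa1 at -0.42, Krt14 at 2.66, Krt6a at 1.51, Angptl4 at 3.19, Dusp6 at 0.88, Etv5 at -2.28 and Mki67 at 2.29. Treated values lay near the added 1 for Etv5 in both experiments and for Dusp6 in the second, so the sizes of these differences are uncertain.

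Other splits of the libraries into groups of the same sizes were counted for every comparison. A share under 0.05 makes chance less likely but does not exclude it. With 35 splits the share cannot fall below 1 of 35, and no adjustment over the comparisons was made. Other splits also mix treated with control libraries. In the comparisons named next only the real split (1) gave as many calls. In tissue this held for the 1-month treatment (4464 calls, at most 475 in 34 other splits), treated against no BBN (753, at most 7) and the 5-day treatment (1043, at most 5). For vehicle against no BBN the 10 splits are too few for a share under 0.05 (4946 calls, at most 4 in the others). In the first cell experiment it held for trametinib (10249, at most 2), the combination against DMSO (10310, at most 1), against trametinib (1049, at most 4) and against rosiglitazone (10903, at most 6342), and for the interaction (272, at most 1 in redraws of residuals). In the second it held for the combination at 24 h (7694, at most 5388) and 72 h (9731, at most 8135), ATRA at 24 h (3554, at most 3) and 72 h (2344, at most 1347), and the differences between times for ATRA (7, at most 1) and the combination (3443, at most 929). It also held for the first minus the second experiment (7075, at most 1). This did not hold for 1 month minus 5 days, where 10 of 100 redraws gave as many calls (1, at most 159). For rosiglitazone alone the splits say nothing on chance: with 0 calls found, all 100 splits give as many whatever the data (at most 2). What set the highest counts in other splits was not tested: 475 came with treated replicate 4 among the vehicles, 6342 with replicates 5 of the combination and of rosiglitazone exchanged, 5388 and 8135 with combination replicate 1 among the DMSO samples, and 1347 with ATRA 72 h replicates 3 and 5 among the DMSO samples.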

How the results depend on the processing

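DESeq2, edgeR, the common scale, equal totals, thinning and the table of 2 groups were tests chosen only after results were seen; the other settings were planned. Of 18213 values of named genes, lists and overlaps, 17223 stayed the same, 863 lost a call, 111 gained one, 6 reversed, and 10 were overlaps that moved at an adjusted p under 0.01. Of 190 counts with 1 library left out, 153 stayed within 1.5 times. No paired analysis was possible because the sample titles carry no numbers that pair libraries of different groups. DESeq2 or TMM on counts was not run for the tissue and the first cell experiment, whose values are not whole reads. The 5-day comparison and the comparisons with DMSO in the first cell experiment hold only the compared groups in any case. Simulated log2 changes of 1 were recovered in 18% of genes in the 5-day tissue and in 84% for trametinib in cells; depth, spread and numbers of samples differ together there, and what depth limits was not separated. The simulated data gave 65 and 178 calls against 1043 and 10249 in the real data, so the real cutoffs were looser.

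Counts moved when 1 library was left out, some of them upward, and the cause was not tested: vehicle against no BBN 3217 to 5191 (4946 with all), treated against no BBN 136 to 595 (753; 136 and 160 without no-BBN replicates 2 and 3, 384 and 470 without treated replicates 2 and 3), 5-day treatment 428 to 1001 (1043; 428 and 531 without vehicle replicates 1 and 3, 602 and 589 without treated replicates 1 and 3), 1 month minus 5 days 0 to 126 (1; also 2, 3 and 6), rosiglitazone 0 to 71 (0; also 1 and 3), its interaction with trametinib 179 to 1205 (272), ATRA at 24 h 2129 to 3432 (3554; 2228 without DMSO replicate 3) and 72 h 1326 to 2528 (2344; 1421 without DMSO replicate 2), and their difference 1 to 160 (7; also 2 and 3). Not moved were the 1-month treatment (3078 to 4737), trametinib (9978 to 10650) and the combination in the first experiment (10027 to 10598).

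With only the compared groups in the fit the counts were 1407 for treated against no BBN (746 shared), 2041 for the combination against trametinib (1006 shared), 731 for ATRA at 72 h (727 shared) and 0 for the difference of ATRA effects; the cause was not tested. Quantile normalisation gave 26 calls for 1 month minus 5 days and 3 for the difference of ATRA effects. No filter gave 2 calls for 1 month minus 5 days and 5 for rosiglitazone, a pseudocount of 4 gave 4 for 1 month minus 5 days, the common scale 75 for rosiglitazone, and DESeq2 29 for the difference of ATRA effects; the cause was not tested. At an adjusted p under 0.01 the 1-month treatment and the combination in cells shared 604 genes (350 higher and 254 lower), where fewer genes are called. The deposited 1-month table of 2 groups gave 3359 calls and thinning at 5 days 1048 (1002 shared). Of 213 list results, 10 remained with an estimated correlation, 210 were found by fry (147 shared) and 206 after quantile normalisation (199 shared). Quantile normalisation also turned the nearly even balance of higher and lower calls for the combination at 72 h (5183 and 4503) and ATRA at 24 h (1813 and 1571) in the second experiment and for trametinib (5004 and 5253) and the combination (5123 and 5211) in the first.

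Reversed were Pdia3 under quantile normalisation with trametinib (0.081), the combination against DMSO (0.105) and against rosiglitazone (0.088), and Spry4 in the first minus the second experiment with a pseudocount of 4 (-1.042). With trametinib fry found the cytokine list lower (adjusted p = 9.72e-06; median 0.13, mean -0.48) and the macrophage list lower (adjusted p = 0.00053; median 0.03, mean -0.23), where camera had the opposite sign and no call. The cause was not tested.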

Other observations

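The list tests in this part were planned, the lists described here were chosen only after the result was seen, and the test of the hypothesis was written before its result.

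Gene groups moved in further comparisons as well. Fatty acid synthesis genes fell with the combination at 72 h in the second cell experiment in 12 of 16 cases and rose in 2, by both counts, with the desaturases Fads2 falling by 3.59 ± 0.22 and Scd2 by 1.48 ± 0.09 and the acetyl-CoA synthetase Acss2 rising by 1.91 ± 0.19 (camera adjusted p = 0.0019; adjusted p = 0.252 with an estimated correlation). Epithelial junction genes rose at 24 h in 13 of 20 cases and fell in 2 (13 and 3 adjusted over the list alone), with Cldn4 at 1.68 ± 0.14 and Cldn1 at -2.74 ± 0.55 (adjusted p = 0.000753; adjusted p = 0.186 with an estimated correlation). Under ATRA at 24 h 3 of 9 fibroblast list genes fell in the cells by both counts, the collagens Col6a2 by 3.07 ± 0.25, Col6a1 by 2.16 ± 0.28 and Col5a1 by 1.11 ± 0.14 (adjusted p = 0.01; adjusted p = 0.163 with an estimated correlation).

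In the tumours, immediate early and heat shock genes fell after 1 month in 9 of 16 cases (12 adjusted over the list alone), such as Atf3 by 2.93 ± 0.53 (adjusted p = 2.04e-05; adjusted p = 0.259 with an estimated correlation), and after 5 days in 6 of 16 (8 adjusted over the list alone), such as Zfp36 by 2.62 ± 0.25 (adjusted p = 0.00011; adjusted p = 0.223 with an estimated correlation). The 1-month means of this list were 14.06 in vehicle replicate 2 and 13.18 and 13.20 in replicates 1 and 3. B and plasma cell genes fell after 1 month in 5 of 13 cases by both counts, with Cd79b falling by 2.60 ± 0.35 (adjusted p = 0.000151; adjusted p = 0.288 with an estimated correlation), and vehicle replicate 2 was again the highest (9.36 against 8.73 and 8.32).

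A hypothesis was that the genes lowered after 5 days of treatment are mostly those that vehicle tumours of the 1-month series expressed above bladder without BBN. Of 899 genes lower at 5 days and 2711 genes higher in vehicle tumours, 629 were shared, where independent lists among 16617 genes would share 146.7, and 4 were lower in both, where 109.6 would be. The log2 changes had r = -0.523 across genes, which are not independent. The comparisons share no library, so the result is consistent with the hypothesis, which says nothing on the cells in which the genes changed.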
